A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

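The deposited table gave, per library and coding sequence, a read count and an RPKM value. Per the file headers the counts were raw, but 2.77% of them were not whole and ended in 0.5. They were handled as estimated counts, in which the authors had apparently split some reads, and were rounded to whole numbers before testing. Whether the split reads overlapped 2 features or matched 2 places in the genome was not checked. The RPKM values, as deposited by the authors, were reads per kilobase of coding length, scaled to the reads of the library, and they were not used for any test. In the 0 h library of series a, the RPKM of the 94 coding sequences of chromosome I had been scaled to 106283 reads. The library total was 4654345, so these values were 43.8-fold larger. Whether 106283 was the number of reads on that chromosome was not checked. The submitters' processing notes name genome build R64. The aligner, the counting tool, their versions and the strandedness of counting are not given in the sources used here.

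Of 65885 lines in the table, 1302 gene and mRNA lines of the 1 h library of series a and 4693 identical second copies, in 11 repeated chromosome blocks of series a, were left out. The remaining 59890 lines were 5989 coding sequences in each of 10 libraries, on 16 nuclear chromosomes. Positions matched the R64 reference exactly for 5981 of them, and 206 overlapped another coding sequence, where counts are uncertain. The table held no mitochondrial genes.

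Counts were tested with edgeR's quasi-likelihood test in all 10 libraries with the time group as the only term. Low counts were filtered with filterByExpr, which left out 46 coding sequences and kept 5943, and libraries were scaled with TMM (factors of 0.8765 to 1.1613). The p-values were adjusted by Benjamini-Hochberg over the genes tested, and genes were called at an adjusted p under 0.05. All tests were two-sided. The biological coefficient of variation was 4.05%, and the replicates of a time differed more than counting error alone gives (chi-square per degree of freedom of 1.94 to 3.08). The p-values rest on this spread between 2 libraries per time, which the design text calls independent replicate experiments; it does not say how the cultures were started. Counting intervals and floors (3 reads, 0.36 to 0.89 CPM by library total) cover counting error only.

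Gene lists were tested with limma's camera at a preset correlation of 0.01, for lists of at least 5 tested members. Of 47 lists fixed, 45 could be tested, and p-values were adjusted over 180 tests (45 lists at 4 times). Of these 86 were called, and 2 were called with an estimated correlation. The lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. The list tests between times, the tests of explanations, the split of lists by series and 2 alternatives, named where they are used, were added afterwards. The list tests between times were adjusted apart from the 180.

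Genes were named by a rule. It took the 8 largest rises and 8 largest falls at each time against 0 h, and 5 of each between times, among genes that passed the test, had all libraries of a time beyond those of the other, and had a mean of at least 10 CPM in the higher group. It added up to 4 members per list, the genes of the series title with their partners, and osmostress and label markers, 229 genes in all.

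The letters a and b mark time series, so libraries of a letter could share an experiment. Deviations of series a from the mean of a time had a Pearson correlation across 5613 genes of -0.115 to 0.314 between times, with genes not independent replicates. A fit with the replicate series as a block called 3248, 3436, 4569 and 4457 genes at the 4 times.

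The pipeline was run on simulated counts with known changes, drawn for each gene independently, with 200 genes changed at 1.5 h. At 1.5 h, edgeR recovered 56% of genes changed 1.25-fold, 88% at 1.5-fold, 91.8% at 2-fold and 98% at 4-fold, and called 9 unchanged genes. At 0.5 h, where none was changed, it called 0. Camera called the 1 list shifted by 1.5-fold and 0 of 40 unchanged lists. Simulated genes were uncorrelated, so this could not test the preset correlation on correlated lists. Nor was a change of most genes simulated (76.5% were called at 1.5 h in the data), so scaling under it was not tested. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.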

Results

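Poly(A)-purified RNA of wild-type BY4741, a laboratory strain of budding yeast, was sequenced before and during growth in 1.5 M KCl. Cells were grown at 30 °C in synthetic complete medium to an OD600 of 0.4 to 0.5, KCl was added, and samples were taken every 30 min up to 2 h. The 10 libraries formed 5 time groups (0, 0.5, 1, 1.5 and 2 h) of 2 libraries each, from replicate time series a and b. The 0 h libraries were the unstressed controls. Reads counted on 5989 coding sequences totalled 3372373 to 4913739 per library in series a. In series b the total was 4676814 at 0 h, and 7851019 to 8325291 at the later times. Levels below are CPM, read counts scaled to a common library total, after scaling by edgeR's TMM factors, as mean ± SD with n = 2. Fold changes are log2 values, and adjusted p-values are from edgeR's quasi-likelihood test unless another test is named. The standard error (SE) of a fold change is the value implied by that test, its absolute log2 value divided by the square root of the F statistic. All levels are shares of the sequenced poly(A) RNA, and the amount of RNA per cell was not measured.

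The libraries separated by time. The largest principal component held 79.3% of the variance and ran from the 0.5 h libraries (-46.94 and -46.47) through 0 h, 1 h and 2 h to the 1.5 h libraries (44.14 and 43.82). The 2 libraries of each time lay within 2 units of each other on all 3 leading components. Of 5943 genes tested, 5449 (91.7%) changed over the course. Against 0 h, 3190 genes changed at 0.5 h, 3384 at 1 h, 4549 at 1.5 h and 4450 at 2 h. Counts of changes of at least 2-fold were far smaller and shifted in direction with time: 48 genes higher and 204 lower at 0.5 h, 417 higher and 110 lower at 1 h, 847 higher and 745 lower at 1.5 h, and 781 higher and 602 lower at 2 h.

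**Figure D1:**
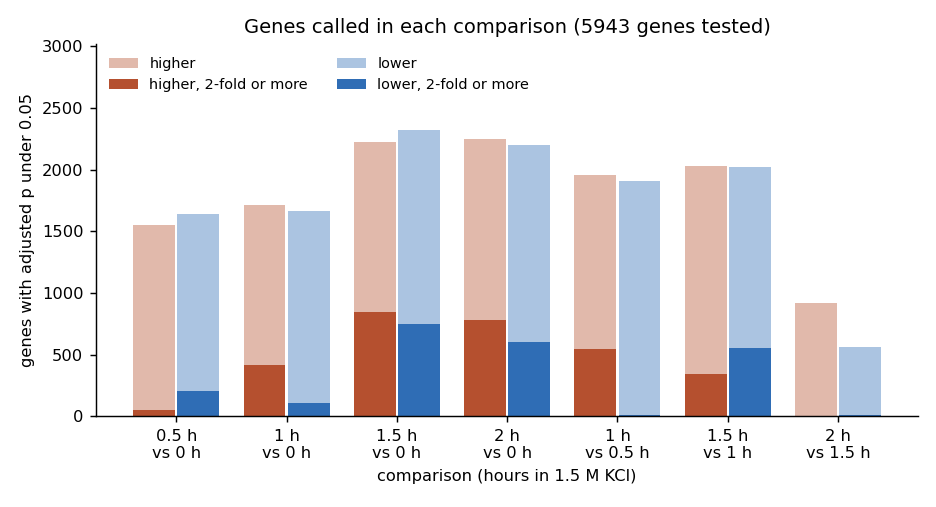
Number of genes with an adjusted p under 0.05 in each comparison, higher (red) and lower (blue), with the part that changed at least 2-fold in the darker shade. Most changes of 2-fold or more at 0.5 h were falls (204 against 48 rises), and most between 0.5 h and 1 h were rises (542 against 9 falls).

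The 0.5 h libraries were compared with 0 h to show the earliest sampled state of the stressed cells. After 0.5 h, genes of growth and protein synthesis were higher and many genes usually called stress genes were lower than before KCl was added. HSP30, which encodes a stress protein of the plasma membrane, fell 31.7-fold, from 1488 ± 36.6 to 47.0 ± 0.857 CPM (log2 fold change -4.99, SE 0.07, adjusted p = 1.3e-20). The polyamine transporter gene TPO2 fell from 1817 to 153 CPM (-3.57, SE 0.07) and its paralog TPO3 from 1220 to 156 CPM (-2.97, SE 0.06). MPC3, which encodes a subunit of the mitochondrial pyruvate carrier, was already 14.9-fold higher (5.88 ± 0.558 to 87.5 ± 0.580 CPM; 3.89, SE 0.14, adjusted p = 1.6e-14). GPD1, the glycerol-3-phosphate dehydrogenase gene of glycerol synthesis, stood at 376 and 380 CPM (0.02, SE 0.05, adjusted p = 0.81). STL1, a glycerol transporter gene, and CTT1, the cytosolic catalase gene, had log2 fold changes of -0.12 (SE 0.12) and -0.17 (SE 0.10), with adjusted p of 0.54 and 0.18. CTT1 was called lower at 0.5 h with library size alone as the scaling (-0.25, adjusted p = 0.048).

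Among the other strong falls at 0.5 h were STP4 (-4.28), CIP1 (-3.85), TDA6 (-3.82), PIC2 (-3.74) and FMP48 (-3.42), each with an SE of at most 0.10. ERR2 is 1 of several near-identical enolase-related genes, between which reads may be shared. Its value of -3.47 rested on 298 reads in 0 h replicate a against 25 in 0 h replicate b, and without that library it was -0.77 (adjusted p = 0.081). Of the genes that rose most, RRT15 (3.66, SE 0.09), YLR154C-G (3.47, SE 0.07), TAR1 (3.16, SE 0.07) and YLR162W (2.62, SE 0.20) share sequence with the 25S ribosomal RNA genes. The share of all reads on these 4 coding sequences was 0.056% and 0.060% in the 0 h libraries and 0.512% and 0.545% at 0.5 h. The S-phase cyclin gene CLB6 rose (1.69, SE 0.18), as did HO, the mating-type switching endonuclease gene (1.55, SE 0.07). FIG1, a mating gene, was called higher (2.28, SE 0.69, adjusted p = 0.0094), but this rested on 0.5 h replicate a (90 reads, against 21 in replicate b), and without that library the change was 0.45 (adjusted p = 0.43).

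Of 138 ribosomal protein genes, 134 rose at 0.5 h and 0 fell, with the same counts adjusted over the list alone. Many of these genes come in near-identical pairs, between which reads may be shared. Their median log2 fold change was 0.48 (camera, adjusted p = 2.8e-20; adjusted p = 0.13 with an estimated correlation). Ribosome biogenesis genes moved with them, 101 of 115 higher and 2 lower (102 and 2 adjusted over the list alone, median 0.42, camera adjusted p = 1.8e-18, and adjusted p = 0.060 with an estimated correlation). All 18 cytosolic tRNA synthetase genes measured were higher (18 adjusted over the list alone, median 0.41, camera adjusted p = 1.6e-06, and adjusted p = 0.082 with an estimated correlation). Of 31 G1/S cell cycle genes, 25 rose and 0 fell (26 and 0 adjusted over the list alone, median 0.49, camera adjusted p = 4.4e-07, and adjusted p = 0.060 with an estimated correlation). Of 53 genes of the DNA polymerases and the replication fork, 36 rose and 2 fell (37 and 2 adjusted over the list alone, median 0.31, camera adjusted p = 7.7e-05, and adjusted p = 0.060 with an estimated correlation). Among them was CDC6, which loads the replicative helicase (21.5 to 53.2 CPM; 1.31, SE 0.12).

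In the other direction, 24 of 27 heat shock and chaperone genes fell and 1 rose at 0.5 h (24 and 3 adjusted over the list alone, median -0.72, camera adjusted p = 2.0e-27, and adjusted p = 0.060 with an estimated correlation). Of 20 trehalose and glycogen genes, 17 fell and 1 rose (17 and 2 adjusted over the list alone, median -1.20, camera adjusted p = 3.0e-21, and adjusted p = 0.060 with an estimated correlation). These included TSL1 of the trehalose synthase complex (479 to 110 CPM; -2.13, SE 0.06) and the glycogen synthase gene GSY2 (302 to 72.0 CPM; -2.07, SE 0.06). Of 33 osmostress targets of the HOG pathway, the yeast signalling pathway for high osmolarity, 17 fell and 3 rose (the same adjusted over the list alone, median -0.39, camera adjusted p = 0.0011, and adjusted p = 0.21 with an estimated correlation). HSP12, a small membrane-associated stress protein gene, was among the 3 that rose (65.0 to 157 CPM; 1.27, SE 0.07). Of 30 cation homeostasis genes, 21 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 3.6e-05, and adjusted p = 0.19 with an estimated correlation), led by the calmodulin-dependent kinase gene CMK2 (-2.70, SE 0.07). Of 28 glycolysis and fermentation genes, 17 fell and 5 rose (the same adjusted over the list alone, camera adjusted p = 2.1e-07, and adjusted p = 0.11 with an estimated correlation). The hexose transporter genes HXT4 (-2.16, SE 0.06) and HXT3 (-1.76, SE 0.05) of this list fell. Of the 3190 genes called at 0.5 h, 48.5% were higher, and with scaling by library size alone 36.6% of 3149 were, but with DESeq2's size factors 55.7% of 3235.

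At 1 h, which was compared with 0 h to show the response after the first 30 min interval, the osmostress genes had turned on. STL1 rose 65.0-fold, from 16.1 ± 0.841 to 1049 ± 6.58 CPM (6.02, SE 0.08, adjusted p = 1.1e-21). GPD1 reached 4580 ± 35.0 CPM (3.61, SE 0.05, adjusted p = 2.9e-21), and CTT1 reached 936 ± 16.6 CPM from 33.7 (4.79, SE 0.07, adjusted p = 8.9e-21). HSP12 rose to 2627 ± 47.9 CPM (5.34, SE 0.07) and the sodium and potassium export pump gene ENA1, which has near-identical copies in its array, to 352 ± 6.70 CPM from 152 (1.21, SE 0.06). MPC3 was the most strongly raised gene named by the rule (125-fold; 6.96, SE 0.11). It was followed by STL1, PHO92, SIP18 (5.81, SE 0.25), the transaldolase paralog gene NQM1 (5.49, SE 0.09), FMP45 (5.42, SE 0.08), HSP12 and the aldehyde dehydrogenase gene ALD3 (5.05, SE 0.06). PHO92 had 4 reads in the 0 h libraries together and 315 at 1 h, a ratio of 63.0 with a 95% counting interval of 24.3 to 233.

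Of the 33 osmostress targets, 29 rose and 3 fell at 1 h (the same adjusted over the list alone), with a median of 3.05 (camera, adjusted p = 1.2e-90; adjusted p = 0.0098 with an estimated correlation). The test at 1.5 h was the only other list test, of 180, that was also called with an estimated correlation. Of 16 genes of glycerol synthesis and transport, 11 rose and 5 fell (the same adjusted over the list alone, median 0.94, camera adjusted p = 6.4e-12, and adjusted p = 0.060 with an estimated correlation). Its glycerol-3-phosphatase gene GPP2 (3.39, SE 0.05) and the dihydroxyacetone kinase gene DAK1 (2.53, SE 0.06) were higher, and without the genes it shares with other lists the list was not called (adjusted p = 0.77). Chaperone genes had reversed, 21 of 27 higher and 1 lower (21 and 2 adjusted over the list alone, median 0.54, camera adjusted p = 5.8e-08, and adjusted p = 0.11 with an estimated correlation). So had trehalose and glycogen genes, 16 of 20 higher and 2 lower (17 and 2 adjusted over the list alone, median 0.74, camera adjusted p = 1.7e-08, and adjusted p = 0.092 with an estimated correlation). In the pentose phosphate pathway 7 of 13 genes rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 4.5e-09, and adjusted p = 0.084 with an estimated correlation). The largest rises were in NQM1, TKL2 (4.76, SE 0.08) and GND2 (4.21, SE 0.08), each a paralog of another member, and SOL4 also rose (1.57, SE 0.08).

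Ribosomal protein genes were back near their 0 h level at 1 h, with 32 higher and 24 lower (30 and 23 adjusted over the list alone), a median of 0.01 and no call (camera, adjusted p = 0.86). That median was -0.01 with DESeq2's size factors and -0.02 with upper-quartile factors. The series differed here. Within series a the median change from 0 h was -0.081 and within series b 0.112, a split looked at after the data were seen. Genes stood apart at an adjusted p under 0.05 in a normal approximation with the common dispersion of the fit, which finds highly counted genes most readily. Of 22 genes that stood apart between the 1 h libraries, 14 were of this list, all lower in series a, and 4 of its genes stood apart at 0 h, all higher in series a. Of the genes outside the list that stood apart at 1 h, only VMA9 was lower in series a. The others, CAN1 among them, were higher in series a. At 0.5 h 4 of 9 genes apart were of this list, at 1.5 h 16 of 29 and at 2 h 5 of 5, all lower in series a. The median change within series a and b was 0.436 and 0.518 at 0.5 h, -1.509 and -1.253 at 1.5 h, and -1.172 and -0.963 at 2 h, so its direction was the same in both series at these times. Ribosome biogenesis genes were lower, 64 of 115 against 4 higher (65 and 5 adjusted over the list alone, median -0.21, camera adjusted p = 0.00031, and adjusted p = 0.28 with an estimated correlation). Of 18 mitotic exit and early G1 genes, 11 fell and 2 rose (the same adjusted over the list alone, median -0.48, camera adjusted p = 0.00024, and adjusted p = 0.092 with an estimated correlation). DSE2, a gene of daughter cell separation, fell from 880 to 230 CPM (-1.92, SE 0.07). The 8 core histone genes were all lower (8 adjusted over the list alone, median -0.53, camera adjusted p = 0.0032, and adjusted p = 0.13 with an estimated correlation). The strongest falls were TPO2 (-4.12), TDA6 (-3.80), CIP1 (-3.78), STP4 (-3.78), TPO3 (-3.18), HAP4 (-2.87), COM2 (-2.83) and HSP30 (-2.60), each with an SE of at most 0.10. HAP4 encodes the activating subunit of a regulator of respiration genes. The 25S rRNA coding sequences held their highest share of reads at 1 h, 1.129% and 1.14%.

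**Figure D2:**
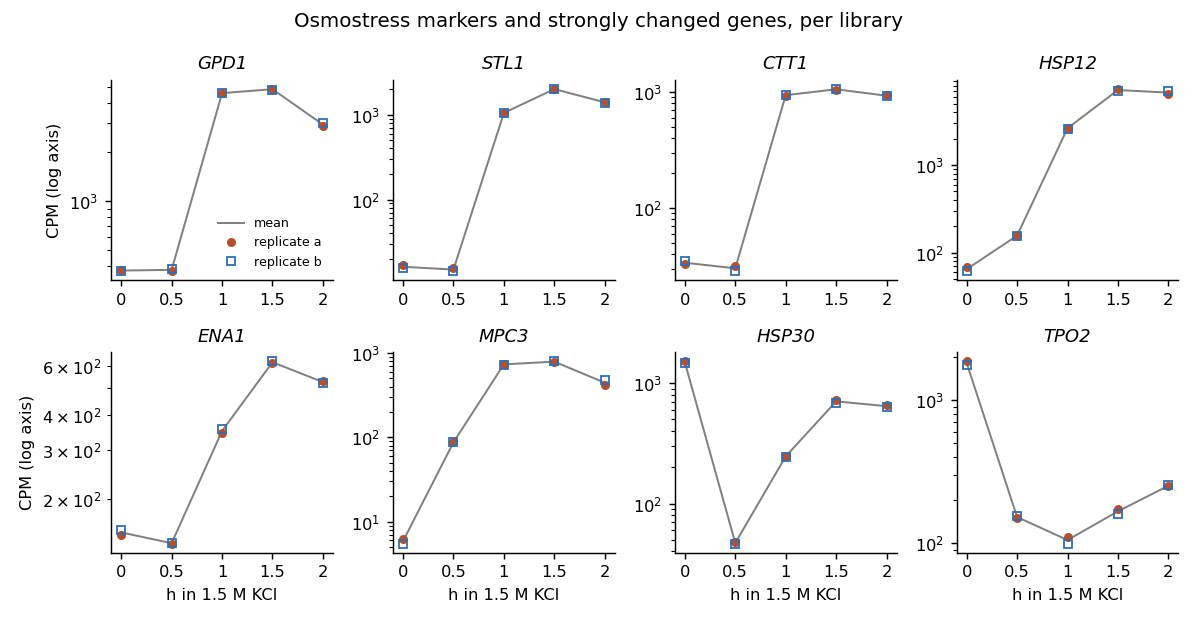
CPM of 8 genes in each library over time in KCl, on log axes. Filled circles are replicate a, open squares replicate b, and the line joins the means; GPD1, STL1 and CTT1 stayed near their 0 h level at 0.5 h and stood at 4580, 1049 and 936 CPM at 1 h, while HSP30 and TPO2 fell to 47.0 and 153 CPM at 0.5 h.

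Comparing 1.5 h with 0 h showed the sampled time with the most changed genes. Protein synthesis genes, which had been higher at 0.5 h, were now lower, and stress, proteolysis and peroxisome genes were higher. All 138 ribosomal protein genes fell (138 adjusted over the list alone), with a median of -1.39 (camera, adjusted p = 3.1e-29; adjusted p = 0.11 with an estimated correlation). All 115 ribosome biogenesis genes fell (115 adjusted over the list alone, median -1.55, camera adjusted p = 1.1e-37, and adjusted p = 0.11 with an estimated correlation). The helicase gene DBP2 went from 588 to 73.0 CPM (-3.01, SE 0.06) and the ribosome assembly GTPase gene NOG1 from 484 to 71.2 CPM (-2.76, SE 0.07). Of 38 translation initiation and elongation factor genes, 37 fell and 0 rose (the same adjusted over the list alone, median -0.997, camera adjusted p = 1.5e-12, and adjusted p = 0.089 with an estimated correlation). All 18 tRNA synthetase genes fell (18 adjusted over the list alone, median -1.33, camera adjusted p = 1.8e-10, and adjusted p = 0.089 with an estimated correlation). Of 19 genes for subunits of RNA polymerases I and III, 17 fell and 0 rose (the same adjusted over the list alone, median -1.23, camera adjusted p = 1.8e-07, and adjusted p = 0.12 with an estimated correlation). Of 54 amino acid biosynthesis genes, 44 fell and 9 rose (the same adjusted over the list alone, median -0.91, camera adjusted p = 1.4e-07, and adjusted p = 0.084 with an estimated correlation). The 3 glycine cleavage genes GCV1 (2.33), GCV2 (2.69) and GCV3 (1.95) went the other way.

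Of the 8 largest rises at 1.5 h by the rule for naming genes, 7 were SIP18 (7.33, SE 0.20), MPC3 (7.07, SE 0.11), STL1 (6.95, SE 0.08), HSP12 (6.78, SE 0.07), SPG4 (6.77, SE 0.14), PHO92 (6.67, SE 0.28) and NQM1 (6.61, SE 0.09). The other, YLR012C, had 1 read in the 0 h libraries together and 243 at 1.5 h, a ratio of 147 with a 95% counting interval of 26.1 to 5820. HSP12 reached 7156 ± 326 CPM, and STL1 2002 ± 20.9 CPM. Of the osmostress targets, 30 rose and 3 fell (the same adjusted over the list alone, median 3.72, camera adjusted p = 3.8e-56, and adjusted p = 0.0098 with an estimated correlation). Of 27 chaperone genes, 26 rose (26 adjusted over the list alone, median 1.46, camera adjusted p = 1.4e-18, and adjusted p = 0.060 with an estimated correlation). HSP26 (4.23, SE 0.08) and SSA3 (4.16, SE 0.06) led them, and HSP30 was the 1 that remained lower (-1.08, SE 0.05). All 36 proteasome list genes rose (36 adjusted over the list alone, median 0.96, camera adjusted p = 2.0e-12, and adjusted p = 0.060 with an estimated correlation). They included RPN4, the activator of proteasome genes (206 to 1005 CPM; 2.28, SE 0.06), and the polyubiquitin gene UBI4 (173 to 1068 CPM; 2.63, SE 0.07). Of 38 autophagy genes, 33 rose and 2 fell (the same adjusted over the list alone, median 1.102, camera adjusted p = 1.0e-04, and adjusted p = 0.11 with an estimated correlation). ATG8 (2.14, SE 0.08) and ATG1 (2.39, SE 0.12) were among those that rose, and UTH1 fell (-1.98, SE 0.05).

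Further lists were called at 1.5 h. Of 34 genes of fatty acid oxidation and the peroxisome, 25 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 6.7e-05, and adjusted p = 0.092 with an estimated correlation), with the thiolase gene POT1 at 3.23 (SE 0.12). Of 29 oxidative stress genes, 23 rose and 3 fell (the same adjusted over the list alone, median 1.05, camera adjusted p = 3.0e-07, and adjusted p = 0.12 with an estimated correlation). Cell wall genes went down, 30 of 38 lower and 4 higher (the same adjusted over the list alone, median -0.78, camera adjusted p = 6.9e-06, and adjusted p = 0.13 with an estimated correlation). Among them were the glucanosyltransferase gene GAS1 (1987 to 354 CPM; -2.49, SE 0.05) and SCW4 (1175 to 269 CPM; -2.12, SE 0.08). The spore wall gene SPS100 rose (5.06, SE 0.09). PMA1, which encodes the plasma membrane proton pump, fell from 8270 to 1375 CPM (-2.59, SE 0.04), while ENA1 rose to 621 ± 5.40 CPM (2.03, SE 0.06). Of 46 meiosis and sporulation genes, 33 were higher and 2 lower (the same adjusted over the list alone, median 0.85, camera adjusted p = 0.0033, and adjusted p = 0.17 with an estimated correlation). After subtracting a per-kilobase background from each library, an alternative chosen after the data were seen, this list was not called (adjusted p = 0.059). TPO2 (-3.45), TPO3 (-3.23), INA1 (-3.23), NDE1 (-2.80) and YBR238C (-2.80) were among the 8 deepest falls, each with an SE of at most 0.09. Of the genes called at 1.5 h, 68.4% were higher with library size alone, against 49% with TMM, and the median log2 change of all genes was 0.311 and -0.008.

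**Figure D3:**
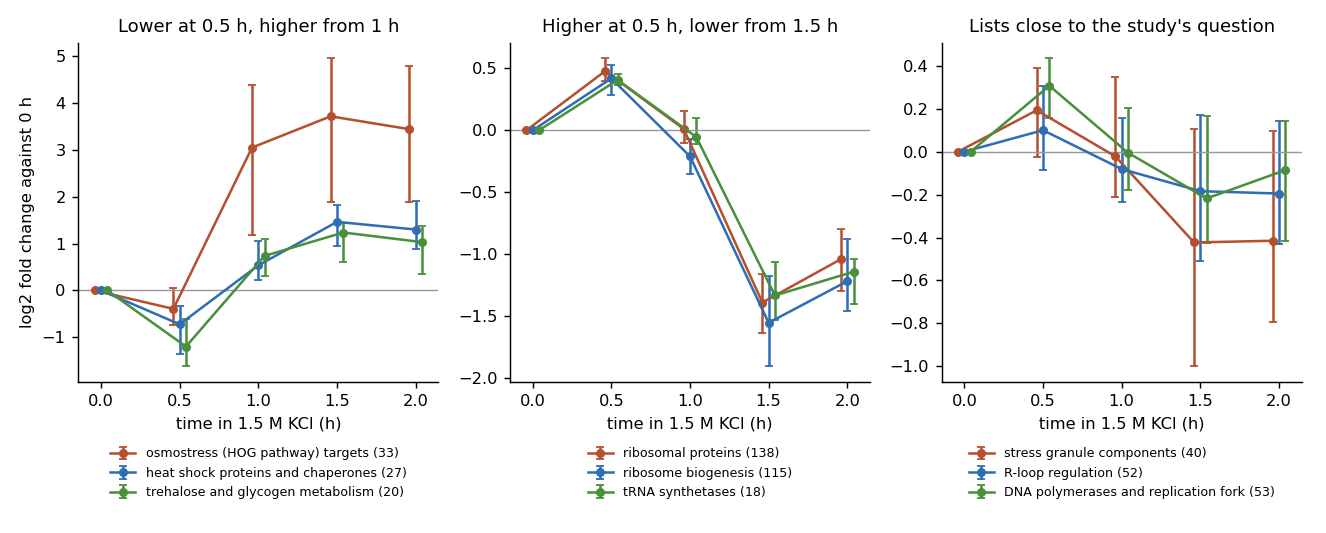
Median log2 fold change against 0 h of 9 gene lists over time, with bars from the lower to the upper quartile of the members and the number of members tested in parentheses; points are shifted sideways so that bars do not overlap. Osmostress targets went from -0.39 at 0.5 h to 3.72 at 1.5 h, and ribosomal protein genes from 0.48 to -1.39; with library size alone as the scaling, the R-loop and replication fork medians at 1.5 h and 2 h were above 0.

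The 2 h libraries, compared with 0 h for the state at the end of the course, differed from it in 4450 genes, 2249 higher and 2201 lower. STL1 stood at 1400 ± 33.2 CPM (6.44, SE 0.08, adjusted p = 2.9e-22), GPD1 at 2939 ± 109 CPM (2.97, SE 0.05) and HSP12 at 6694 ± 355 CPM (6.69, SE 0.07). ENA1 was at 527 ± 8.09 CPM (1.79, SE 0.06). Of the osmostress targets 31 were higher and 1 lower (the same adjusted over the list alone, median 3.44, camera adjusted p = 9.0e-60, and adjusted p = 0.060 with an estimated correlation). Of the ribosomal protein genes 135 were lower and 0 higher (the same adjusted over the list alone, median -1.04, camera adjusted p = 1.6e-22, and adjusted p = 0.12 with an estimated correlation). All 36 proteasome list genes were higher (36 adjusted over the list alone, median 1.04, camera adjusted p = 6.1e-15, and adjusted p = 0.084 with an estimated correlation). All 8 core histone genes were lower (8 adjusted over the list alone, median -1.04, camera adjusted p = 0.00097, and adjusted p = 0.089 with an estimated correlation). Histone HTA1 fell from 1045 to 446 CPM (-1.23, SE 0.05). At 1.5 h the 8 histone genes were also lower, but the list was not called (camera, adjusted p = 0.062). It passed the threshold with some alternatives, among them the replicate series as a block (camera, adjusted p = 0.046) and limma-voom (0.0039), but not with an estimated correlation. The fry test, which does not compare a list with other genes, also called it (adjusted p = 6.3e-06).

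The 8 deepest falls at 2 h by the rule were CAN1, INA1, MFA1, TPO2, ZRT1, MRH1, MFA2 and SCW4. The arginine permease gene CAN1 fell from 68.1 ± 2.95 to 6.04 ± 2.996 CPM (-3.31, SE 0.36, adjusted p = 7.2e-08) and the zinc transporter gene ZRT1 from 2190 to 324 CPM (-2.76, SE 0.06). The genes of the a-factor pheromone, MFA1 (367 to 45.7 CPM; -2.96, SE 0.17) and MFA2 (379 to 53.9 CPM; -2.73, SE 0.15), were lower too, as were MRH1 (-2.73, SE 0.06) and SCW4 (-2.60, SE 0.08). Of 7 markers of the a mating type, 6 fell and 0 rose (the same adjusted over the list alone, median -1.48, camera adjusted p = 0.00036, and adjusted p = 0.12 with an estimated correlation). Of 5 alpha-cell markers, 2 rose and 0 fell (the same adjusted over the list alone), and the list was not called (camera, adjusted p = 0.46). These were STE3 (10.6 to 45.8 CPM; 2.09, SE 0.14) and MF(ALPHA)1 (0.92 to 12.9 CPM; 3.76, SE 0.37). At 2 h, 50.5% of the called genes were higher with TMM and 68.2% with library size alone, and the median log2 change of all genes was 0.011 and 0.294.

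Successive times were compared to show when the profile moved. Between 0.5 h and 1 h, 3862 genes changed, 1955 higher and 1907 lower (50.6% higher, against 44.2% with DESeq2's size factors and 58.8% with library size alone), and of those that changed at least 2-fold 542 were higher and 9 lower. STL1 (6.14, SE 0.08), NQM1 (5.21, SE 0.08), ALD3 (5.11, SE 0.06), CTT1 (4.97, SE 0.07) and GRE1 (4.87, SE 0.12) rose most. DSE2 (-1.70, SE 0.07), CAN1 (-1.61, SE 0.29), the chitinase gene CTS1 (-1.17, SE 0.05), ZRT1 (-1.10, SE 0.05) and MNN1 (-1.06, SE 0.07) fell most. The call for CAN1 was lost with DESeq2's Wald test (adjusted p = 0.061), and its 1 h libraries lay apart, at 37.5 CPM in series a and 13.5 in series b. Between 1 h and 1.5 h, 4051 genes changed, 2028 higher and 2023 lower. Of these 50.1% were higher, against 61.1% with upper-quartile factors and 75.8% with library size alone. The largest falls in that interval were DBP2 (-2.73, SE 0.06), the ribosome-associated Hsp70 genes SSB1 (3493 to 546 CPM; -2.68, SE 0.05) and SSB2 (2868 to 493 CPM; -2.54, SE 0.05), whose near-identical sequences may share reads, the nuclear import receptor gene KAP123 (-2.49, SE 0.06) and the CTP synthase gene URA7 (-2.43, SE 0.07). The largest rises were LSO1 (3.64, SE 0.18), the proline oxidase gene PUT1 (3.06, SE 0.10), YPR145C-A (2.91, SE 0.17), ADE17 (2.74, SE 0.06) and PHO89 (2.53, SE 0.11).

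Between 1.5 h and 2 h the profile moved least, with 1485 genes changed, 922 higher and 563 lower, and 1 higher and 7 lower by at least 2-fold. The 62.1% that were higher became 50.2% with upper-quartile factors and 49.1% with library size alone. The count itself was 766 with DESeq2's Wald test and 859 without 2 h replicate b. Of the ribosomal protein genes 101 rose and 0 fell (112 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 2.4e-24, and adjusted p = 0.14 with an estimated correlation). Of 28 glycolysis and fermentation genes 17 rose and 3 fell (18 and 3 adjusted over the list alone, median 0.30, camera adjusted p = 8.8e-12, and adjusted p = 0.10 with an estimated correlation). The median of this list at 2 h was still below 0 h, by -0.266 within series a and -0.187 within series b. Of the osmostress targets 16 fell and 5 rose (17 and 5 adjusted over the list alone, median -0.19, camera adjusted p = 2.2e-07, and adjusted p = 0.10 with an estimated correlation). MPC3 fell from 792 to 446 CPM (-0.82, SE 0.06) and the cell surface gene ZPS1 from 386 to 204 CPM (-0.94, SE 0.06). NCA3 (1.23, SE 0.07), BSC1 (0.96, SE 0.12), YGL188C-A (0.95, SE 0.21) and YRO2 (0.94, SE 0.06) rose. MIN10 also rose (0.97, SE 0.19), and without 2 h replicate b its call was lost (adjusted p = 0.056). The calls of YLR157C-C (-1.92), YLR156C-A (-1.74) and YLR159C-A (-1.57), which overlap 5S rRNA genes, were lost without 1.5 h replicate a (-0.44, -0.37 and -0.11).

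The 0.5 h and 2 h libraries were compared directly to test whether the early state differed from the late one. They differed in 4802 genes, 2571 higher and 2231 lower at 2 h. Of the called genes 53.5% were higher with TMM and 71.0% with library size alone, and the median log2 change of all genes was 0.072 and 0.432. STL1 (6.56, SE 0.08), SIP18 (6.19, SE 0.16), NQM1 (6.05, SE 0.08), GRE1 (6.01, SE 0.11) and ALD3 (5.997, SE 0.06) were highest at 2 h against 0.5 h. CAN1 (-3.30, SE 0.35), the transcription factor gene SFG1 (-3.09, SE 0.08), the acid phosphatase gene PHO3 (-3.08, SE 0.07), INA1 (-3.03, SE 0.06) and MFA2 (-2.98, SE 0.15) were lowest.

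The series title names Pol32, RNase H1, R-loops (RNA paired with DNA) and stress granules (cytoplasmic assemblies of mRNA and protein), so their genes were reported whatever their result. Positions are those of coding sequences in genome build R64. POL32 (YJR043C, chromosome X, 516461 to 517513), a subunit gene of DNA polymerase delta, rose from 31.2 ± 3.05 to 41.6 ± 1.89 CPM at 0.5 h (0.41, SE 0.11, adjusted p = 0.0052). It stood at 27.9 ± 1.81 CPM at 1 h (-0.18, SE 0.12, adjusted p = 0.22) and was lower at 1.5 h (21.1 CPM; -0.56, SE 0.12, adjusted p = 0.00036) and at 2 h (23.6 CPM; -0.41, SE 0.12, adjusted p = 0.0052). The 0.5 h call was lost without 0 h replicate a (0.31, adjusted p = 0.070), and the 2 h call without 0 h replicate b (-0.31, adjusted p = 0.074) or 2 h replicate b (-0.36, adjusted p = 0.072). With library size alone as the scaling POL32 was at -0.25 at 1.5 h (adjusted p = 0.075) and -0.13 at 2 h (adjusted p = 0.34). The catalytic subunit gene POL3 (YDL102W, chromosome IV, 276872 to 280165) followed the same course (0.34, 0.08, -0.34 and -0.30 at the 4 times, SE 0.08 each). All but the 1 h value were called, and with library size alone the late values were -0.02 and -0.01 and were not called. POL31 (YJR006W, chromosome X, 449202 to 450665) was called only at 1.5 h (-0.21, SE 0.09, adjusted p = 0.034), and not when any 1 of the 4 libraries of 0 h and 1.5 h was left out (-0.18 to -0.24, adjusted p of 0.051 to 0.15). With library size alone it was at 0.11 at 1.5 h (adjusted p = 0.26).

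RNH1 (YMR234W, chromosome XIII, 740266 to 741312), the RNase H1 gene, was lower from 1 h on. It stood at 68.8 ± 0.646 CPM at 0 h, 62.5 ± 6.24 at 0.5 h (-0.16, SE 0.08, adjusted p = 0.12), 56.0 ± 0.674 at 1 h (-0.29, SE 0.09, adjusted p = 0.0068), 53.6 at 1.5 h (-0.36, SE 0.08, adjusted p = 0.00060) and 43.1 at 2 h (-0.67, SE 0.09, adjusted p = 8.7e-07). With library size alone the 1.5 h value was -0.04 (adjusted p = 0.66), and without 0.5 h replicate a the 0.5 h value was -0.24 (adjusted p = 0.035). Of the RNase H2 genes, RNH201 (YNL072W, chromosome XIV, 490317 to 491240), the catalytic subunit gene, rose at 0.5 h (0.66, SE 0.14, adjusted p = 0.00045) and 1 h (30.5 ± 2.41 to 57.5 ± 1.64 CPM; 0.92, SE 0.13, adjusted p = 9.5e-06). It was at 0.04 at 1.5 h, where the replicates lay apart (SD 8.37 CPM), and without 1.5 h replicate b it was called at 0.34 (adjusted p = 0.030). The same gene was called at 0.36 with library size alone (adjusted p = 0.026). RNH202 rose at 0.5 h (0.47, SE 0.10) and had no call later, and RNH203 was lower at 1.5 h (-0.60, SE 0.17) and 2 h (-0.81, SE 0.18). The 1.5 h call of RNH203 was lost without 0 h replicate a (-0.47, adjusted p = 0.060) and with library size alone (-0.28, adjusted p = 0.14). The R-loop list of 52 genes was not called at any of the 4 times (camera, adjusted p of 0.15, 0.67, 0.30 and 0.31). Its members went both ways, 18 higher and 9 lower at 0.5 h and 12 higher and 25 lower at 2 h (18 and 9, and 11 and 25, adjusted over the list alone). DBP2, the exosome helicase gene MTR4 (-2.26, SE 0.06) and STM1 (-1.45, SE 0.05) fell most at 1.5 h, and SEM1 rose (1.146, SE 0.10).

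**Figure D4:**
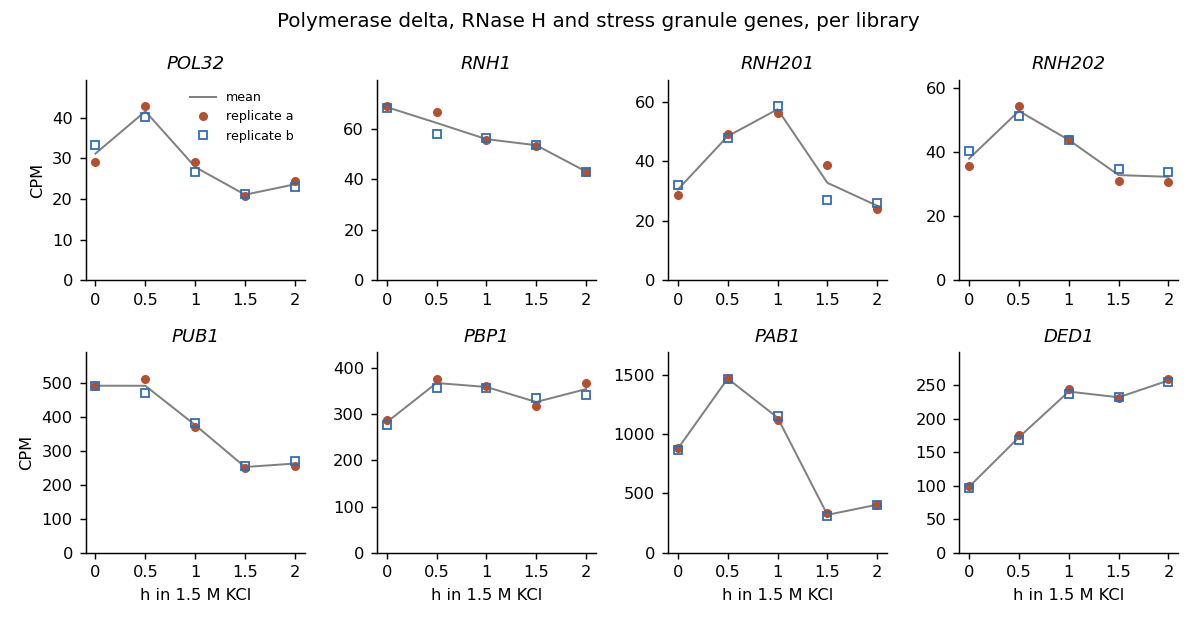
CPM of 8 genes of DNA polymerase delta, RNase H and stress granules in each library over time in KCl, on axes that start at 0. Filled circles are replicate a, open squares replicate b, and the line joins the means; POL32 peaked at 41.6 CPM at 0.5 h, RNH1 ended at 43.1 CPM, and PAB1 went from 1466 CPM at 0.5 h to 319 at 1.5 h while DED1 rose to 257 CPM at 2 h.

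The stress granule marker genes went different ways. PAB1 (YER165W, chromosome V, 510373 to 512106), the poly(A)-binding protein gene, rose from 876 ± 13.9 to 1466 ± 0.851 CPM at 0.5 h (0.74, SE 0.05, adjusted p = 7.3e-10). It then fell to 319 ± 17.9 CPM at 1.5 h (-1.46, SE 0.05, adjusted p = 4.1e-15). PUB1 (YNL016W, chromosome XIV, 602907 to 604268) stood at 492 CPM at both 0 h and 0.5 h and fell to 252 ± 4.92 CPM at 1.5 h (-0.96, SE 0.06, adjusted p = 6.6e-12). The RNA helicase gene DED1 (YOR204W, chromosome XV, 722911 to 724725) rose at all 4 times, from 98.3 ± 2.62 to 257 ± 4.06 CPM at 2 h (1.38, SE 0.06, adjusted p = 4.3e-14). PBP1 (YGR178C, chromosome VII, 851047 to 853215) was higher at all 4 times, by 0.38, 0.34, 0.21 and 0.32 (SE 0.06 each). Of the 40 stress granule genes measured, 20 rose and 7 fell at 0.5 h (21 and 7 adjusted over the list alone, camera adjusted p = 0.047, and adjusted p = 0.13 with an estimated correlation). At 1.5 h 10 rose and 25 fell (the same adjusted over the list alone, median -0.42, camera adjusted p = 0.016, and adjusted p = 0.11 with an estimated correlation), and at 2 h 10 rose and 26 fell (camera, adjusted p = 0.047, and adjusted p = 0.17 with an estimated correlation). The 0.5 h call was lost without either 0 h library (adjusted p of 0.085 and 0.056), and the 2 h call without 2 h replicate a (0.054), 0 h replicate b (0.053) or 2 h replicate b (0.056). None of the 3 calls held with library size alone (adjusted p of 0.085, 0.051 and 0.12). The list shares translation factor genes such as TIF4631 (-1.85 at 1.5 h, SE 0.07) with another list. Without shared genes it was not called at any of these times (adjusted p of 0.59, 0.48 and 0.70). The P-body and mRNA decay list of 38 genes was not called at any time (camera, adjusted p of 0.49, 0.85, 0.85 and 0.96). Its decapping scavenger gene DCS1 rose at 1.5 h (69.2 to 313 CPM; 2.18, SE 0.07) and PAT1 fell (-0.96, SE 0.06).

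Marker genes were read against the labels. The a-cell receptor gene STE2 stood at 990 ± 33.8 CPM at 0 h, and the alpha-cell receptor gene STE3 at 10.6 CPM. The a-cell markers MFA1, MFA2, BAR1 and STE6 also stood above every alpha-cell marker at 0 h. Other markers did not separate the types. By library total, without TMM, the alpha-cell marker SAG1 stood at 66.0 and 82.5 CPM in the 0 h libraries. That was above the a-cell markers AGA2 (51.8 and 44.9) and ASG7 (12.7 and 11.1). By 2 h STE2 had fallen to 356 CPM and STE3 had risen to 45.8 CPM. LEU2 and MET17, which BY4741 lacks, had 0 reads in all 10 libraries, which allows up to 0.36 to 0.89 CPM (by library total, without TMM) from 3 reads. HIS3 had at most 7 reads. URA3 had 162 reads (37.6 CPM) in 0.5 h replicate a and at most 5 in any other library.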

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

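All 10 tests of explanations in this part were chosen only after the result they bear on was seen, as were the list tests between 0.5 h and 2 h.

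For 13 lists the change at 0.5 h and the change at 2 h, both against 0 h, had opposite signs and were both called, which is what flagged them. The test of 2 h against 0.5 h, in the same libraries, also called each with the preset correlation, but 2 opposite calls all but fix that outcome, so it adds no support of its own. The median log2 change from 0.5 h to 2 h was 3.483 for osmostress targets, 2.592 for heat shock proteins and chaperones, 2.184 for trehalose and glycogen metabolism and 1.171 for autophagy. It was -1.565 for ribosomal proteins, -1.568 for ribosome biogenesis, -1.372 for RNA polymerases I and III, -1.166 for translation factors and -1.575 for tRNA synthetases. It was -0.436 for stress granule components, -1.214 for G1/S genes, -0.907 for G2/M genes and -1.01 for amino acid biosynthesis. With an estimated correlation the adjusted p of these 13 tests was 0.1028 to 0.2433, so none was called. The 0.5 h call of autophagy (adjusted p = 0.0475) was lost with the replicate block (0.054), with library size alone (0.074) and without 0 h replicate b (0.11).

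Reads also stood above both 0 h libraries in coding sequences that the filter had left out. In 1.5 h replicate b there were 12 reads on YBR200W-A, 15 on TYC1, 15 on YHR214C-E, 26 on YKL102C, 11 on YNR077C and 13 on YPL152W-A. In 2 h replicate b there were 12 on YCR108C, 12 on YKL097C, 15 on YPL152W-A and 14 on YPR159C-A. In 0.5 h replicate a there were 162 on URA3. The rule set a least number of reads, which favours deep libraries. Replicate b held 8060498 reads at 1.5 h and 8016636 at 2 h, against 4654345 and 4676814 in the 0 h libraries. Apart from URA3 the levels were 1.36 to 3.23 CPM by library total. In both these libraries the 1st percentile of reads per kilobase was 51.2, so background was not excluded for these counts.

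Coding sequences with 25S rRNA sequence (TAR1, YLR154C-G, YLR162W and RRT15) rose after KCl in both series. Carry-over of rRNA that varies from library to library, whatever the time, was argued against. The range of the time means was at least 6.45 times the largest difference between series. The rule that named these genes had set both 0.5 h libraries beyond both 0 h libraries, so part of that range was fixed beforehand. Carry-over shared by both libraries of a time was not tested. A single 25S source that rises by a common factor was argued against too, since YLR154C-G and TAR1, which both lie wholly inside 25S genes, differed by 1.05 (log2, SE 0.09) at 1.5 h. They were compared at that time only, and they lie on opposite strands, with the strandedness of counting unknown. A change of rRNA or its poly(A) tails with time in KCl stays open. Each of the 4 coding sequences rose at 0.5 h by at least 2.34 (log2) in both series, and the poly(A) purification acts on the same RNA. For the 5S coding sequences time in KCl alone was argued against, since series a exceeded series b at least 3.51-fold at 1.5 h.

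URA3, which BY4741 lacks, had 162 reads in 0.5 h replicate a. Expression of URA3 at 0.5 h in KCl was argued against by 0 URA3 reads in 0.5 h replicate b. Cells of a strain with intact LEU2 and MET17 gave no sign, with 0 reads of these genes in that library, but a strain that lacks them stays open. RNA or DNA of another strain or construct that carries URA3 also stays open. At an adjusted p under 0.05, 9 genes stood apart between the 0.5 h libraries, 2 of them (URA3 and FIG1) at least 4-fold. The count includes URA3 itself, so the test could not have come out against this explanation. Nor can it tell a construct from another strain.

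The genes of lowest level at 0 h rose by 1.5 h. For 594 genes picked by their 0 h level in series a, the median log2 rise in series b was 1.27 (95% interval 1.17 to 1.36), which argues against picking genes by low chance counts. The intervals in this paragraph come from resampling genes within single libraries of series b, so they leave out the spread between libraries. An even background was set at the 1st percentile of reads per kilobase of each library. After subtracting it the rise was 0.94 (0.80 to 1.08), which argues against a background of that size as the whole cause. An even background above that percentile stays open. The subtracted level itself rose, from 0.93 and 1.09 RPKM in the 0 h libraries to 7.46 and 6.36 at 1.5 h. At 1 h the subtraction took the median rise in series b from 0.64 to 0.24. Without subtraction, the rise at 1.5 h exceeded the change of 594 genes of middle level by 1.28 (1.16 to 1.38), which argues against a share freed by falling abundant genes. A background that is uneven between genes was not tested, and neither was the total amount of mRNA, so a rise of low genes in KCl itself remains only a hypothesis.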

How the results depend on the processing

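The subtraction of a background per kilobase and the removal of coding sequences with rRNA sequence were chosen after the data were seen; all other alternatives were planned. Over the alternatives, 226 of 239 counts stayed within 1.5 times the count reported, and 13 moved. This compares the size of counts, not the genes in them. With library size alone 4795 genes were called at 1.5 h, and 3791 of them were among the 4549 reported. For a comparison of 2 times, most fits without 1 library kept all libraries of both times, so those counts had little room to move. Of 4496 values of list tests 4259 kept direction and side of the threshold, 130 lost the call, 107 gained one and 0 reversed. Of 20941 values of named genes 20576 kept both, 280 lost the call, 77 gained one and 8 reversed.

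With a limit of 2-fold added, the counts were 252 (0.5 h), 527 (1 h), 1592 (1.5 h) and 1383 (2 h) against 0 h, 551 (0.5 h to 1 h), 902 (1 h to 1.5 h), 8 (1.5 h to 2 h) and 1875 (0.5 h to 2 h), since the limit removes smaller changes. Between 1.5 h and 2 h, DESeq2's Wald test called 766 and an adjusted p under 0.01 called 863. Without 1 library that count was 859 (without 2 h replicate b) to 1590. Leaving out 1 library gave 2518 to 3190 genes at 0.5 h, 2735 to 3364 at 1 h, 4224 to 4548 at 1.5 h and 4013 to 4446 at 2 h, with the lone library of a time assumed to vary like the other groups. Of 180 list tests, camera with an estimated correlation called 2, both of osmostress targets, and fry, which does not compare a list with other genes, called 159.

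With library size alone, CMK2 (0.1085), FMP48 (0.1691) and POL31 (0.1071) at 1.5 h and ZPS1 at 2 h (0.0709) reversed; with that scaling the median of all genes was 0.311 at 1.5 h (-0.008 as reported) and 0.294 at 2 h (0.011). ERR2 at 1 h was 1.3892 without 0 h replicate a and -2.2057 without 0 h replicate b. After background subtraction OSW1 at 1 h was 0, CLB6 at 1.5 h -0.2245 and FMP48 at 1.5 h 0.0271. The cause was not tested for the other moves. The replicate block, where it could be set against the reported fit, changed 3 list calls, of autophagy at 0.5 h (adjusted p = 0.054), mating at 2 h (0.055) and histones at 1.5 h (0.046), and calls of genes near the threshold.

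Not run were a removal of mitochondrial and non-coding genes, since the table has only nuclear coding sequences, and alternatives for normalized values, since it has counts. The test over the whole course has no value with 4 libraries only. Depth limits genes with few reads, where 3 reads were 0.36 to 0.89 CPM.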

Other observations

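The list tests of this part were planned, and the genes were named by the rule. At 1.5 h, 19 of 27 ergosterol synthesis genes fell and 2 rose (the same adjusted over the list alone, median -0.58, camera adjusted p = 0.0081, and adjusted p = 0.13 with an estimated correlation). ERG11 fell from 1089 to 306 CPM (-1.83, SE 0.05) and ERG3 from 590 to 159 CPM (-1.88, SE 0.06). Of 34 purine and pyrimidine synthesis genes 23 fell and 8 rose (the same adjusted over the list alone, median -0.98, camera adjusted p = 6.7e-05, and adjusted p = 0.13 with an estimated correlation), with the GMP synthase gene GUA1 going from 927 to 166 CPM (-2.48, SE 0.06). Of 28 methionine and sulfur genes 20 rose and 4 fell (the same adjusted over the list alone, median 0.65, camera adjusted p = 0.0080, and adjusted p = 0.18 with an estimated correlation), among them SAM2 (2.01, SE 0.07) and MET6 (1.89, SE 0.06). The list was not called at 2 h (camera adjusted p = 0.10), where limma-voom called it (adjusted p = 0.018) but an estimated correlation did not.

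The DNA damage response list of 55 genes was not called at any time (camera adjusted p of 0.59, 0.78, 0.21 and 0.17), while 32 of its genes were higher and 8 lower at 1.5 h (the same adjusted over the list alone). RNR3, a ribonucleotide reductase gene, rose from 11.2 to 42.5 CPM at 1.5 h (1.93, SE 0.17). The list of osmosensing and HOG signalling genes, 30 in number, was not called at any time either (camera adjusted p of 0.46, 0.24, 0.85 and 0.94).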
